A study of Homo sapiens with 22 samples.

How the data were processed

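Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was described for 22 libraries of MLL-AF9 leukaemia cell lines, 15 from NOMO-1 and 7 from THP-1 cells. The libraries covered BMAL1 (ARNTL), CLOCK, control IgG and input, with further libraries labelled biotin. Cells were fixed with ethylene glycol bis(succinimidyl succinate) (EGS), a long-armed protein crosslinker, before formaldehyde in all but the biotin libraries. Peak lists of 2 libraries were used here, BMAL1 and CLOCK in THP-1 cells fixed with 2 mM EGS for 30 minutes and 1% formaldehyde for 30 minutes. Per the labels, 3 libraries entered the final analysis of the study, namely these and the THP-1 input of the same fixation. The other 20 libraries, including IgG, input and every NOMO-1 library, were not analysed here.

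Per the labels' protocols, chromatin was sonicated, immunoprecipitated overnight, and sequenced as paired-end libraries. The submitters' processing notes name Bowtie 0.12.7, SAMtools 1.2, Picard and HOMER 4.7.2 and the genome build hg19, without the role or order of each. The deposited peak lists name HOMER as the peak caller in their source columns. The score of each peak is the authors' own value, deposited without a stated unit, normalization or threshold. Scores were multiples of 0.5 in both lists. Because nothing states that the lists share a scale, scores were used to describe, rank or filter peaks within a list, with 2 exceptions. Their relation between lists was described by a correlation over shared peaks, and the lowest CLOCK score, 18, was applied to the BMAL1 list as a stricter limit, which does not make the lists comparable. The control used in peak calling and the filters applied are not given in the sources used here. Each list came from 1 library, so peaks were called per library. The authors' deposited table of common regions was compared with both lists. Sequencing depth per library is unknown from these files.

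A CLOCK peak was counted as shared when it overlapped a BMAL1 peak by at least 1 bp. The count was compared with 10000 random placements of the CLOCK peaks on their own chromosomes, with widths kept, between the first and last peak of either list, in a one-sided permutation test. The median score of shared peaks was placed among 10000 random lists of the same size from the same factor. Pearson and Spearman correlations over shared peaks were tested with 100000 permutations, two-sided. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only. With 1 library per factor there was no replicate check, and each p-value describes the placement or pairing of peaks in these libraries, not a spread between cultures. Regions named in the text are the 10 highest-scoring peaks of each factor and the 10 shared peaks with the best worst rank over both lists, with ties broken by chromosome and start. Other regions named were chosen after their values were seen.

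These tests, their alternatives and the rule for named regions were set before the data were examined, except for the alternatives and tests named as later additions. Alternatives covered stricter score limits, other definitions of overlap, another random placement, merging of peaks within 1000 bp and restriction to chromosomes 1 to 22 and X. The overlap count was tested on simulated data, in which 50 planted overlaps among 269 CLOCK peaks were recovered in each of 5 draws. Of 20 draws with none planted, 0 gave a permutation p below 0.05. For 140 pairs of simulated values, drawn from a normal distribution and not from peak scores, a planted correlation was detected in 20 of 20 draws. A permutation test called 1 of 20 draws with none planted. These simulations check the calculations, not the power for the correlation found here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No genome or gene annotation of build hg19 was used here, so regions are given by hg19 coordinates, and planned tests of promoters, E-box sequences and gene lists were not run.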

Results

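The binding sites of the circadian transcription factors BMAL1 and CLOCK were mapped by ChIP-seq in THP-1, a human monocytic leukaemia cell line carrying the MLL-AF9 fusion. BMAL1 and CLOCK bind DNA as a heterodimer and form the positive arm of the circadian feedback loop. Peak lists from 1 BMAL1 library and 1 CLOCK library were compared, so no value below has a replicate error. Coordinates are those of build hg19.

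Far more BMAL1 sites than CLOCK sites were listed. The BMAL1 list held 9584 peaks and the CLOCK list 269, a ratio of 35.6. Against BMAL1 peaks scoring 18 or more, the lowest CLOCK score, the ratio was 11.7, although the lists are not stated to share a scale. BMAL1 scores ran from 10 to 320.5 with a median of 14.5 and quartiles of 11.5 and 20. CLOCK scores ran from 18 to 169 with a median of 24 and quartiles of 19.5 and 32.5. Peak numbers, which followed score within each chromosome, had gaps amounting to 93.1% of the CLOCK numbers and 32.1% of the BMAL1 numbers (highest numbers summed over chromosomes, 3924 and 14124). The difference in number cannot be separated from a difference in threshold, antibody, depth or the loss of ranked entries. With both end positions counted, all CLOCK peaks spanned 533 bp and 9583 BMAL1 peaks spanned 397 bp. The remaining BMAL1 peak, chr15:102521041-102521385, spanned 345 bp.

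The strongest BMAL1 peaks lay close together on chromosome 1. The highest score, 320.5, was at chr1:43938201-43938597, with a neighbour at chr1:43941563-43941959 scoring 265. Farther upstream, chr1:40968311-40968707 scored 302.5 and chr1:40399926-40400322 scored 255. A group of 3 peaks followed at chr1:40542628-40543024, chr1:40545636-40546032 and chr1:40516460-40516856, with scores of 209.5, 206 and 201.5. The other members of the top 10 were chr10:125919398-125919794 with 175, chr5:400106-400502 with 173.5 and chr19:13210838-13211234 with 155. None of these 10 BMAL1 peaks overlapped a CLOCK peak, a share of 0% with an exact 95% interval reaching 30.8%. Over the whole list 1.46% of 9584 BMAL1 peaks overlapped one, so 0 of 10 does not set these peaks apart. Of these peaks 7 lay on chromosome 1, where 1831 of 1856 CLOCK peak numbers were absent from the list, 334 of them between peaks scoring 116 and 48, so a CLOCK peak at these sites cannot be excluded. From 40 to 44 Mb of chromosome 1, a region chosen after its values were seen, 39 BMAL1 peaks had a median score of 56. The other 1148 peaks of chromosome 1 had a median of 16.

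**Figure D1:**
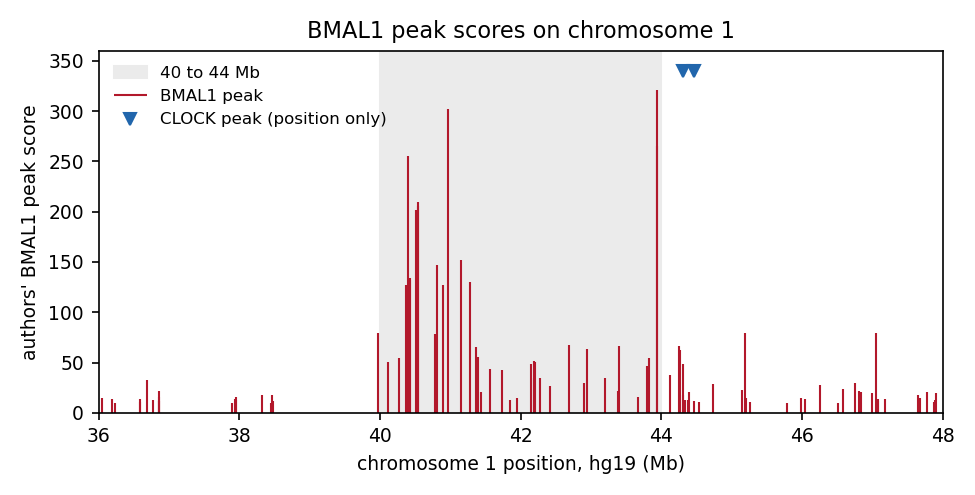
BMAL1 peaks between 36 and 48 Mb of chromosome 1 (hg19, horizontal axis in Mb), each drawn as a line with its height at the authors' score, and CLOCK peaks as triangles marking position only. The shaded 40 to 44 Mb held 39 BMAL1 peaks with a median score of 56 and 0 CLOCK peaks, and the nearest CLOCK peak, chr1:44300188-44300720, lies just past the edge of this region, which was chosen after its values were seen.

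Every one of the 10 highest-scoring CLOCK peaks overlapped a BMAL1 peak, against 52.0% of all 269 CLOCK peaks. The highest was chr22:18687946-18688478 with a score of 169. It was followed by chr16:33889126-33889658 with 126.5, chr4:2414618-2415150 with 124.5, chr19:49140797-49141329 with 118.5 and chr1:229203821-229204353 with 116. Next came chrX:153523642-153524174 with 111.5, chr10:88730962-88731494 with 99.5 and chr17:8059760-8060292 with 92.5. The last were chr11:45868573-45869105 with 87 and chr12:26267290-26267822 with 78.5. Midpoints of these CLOCK peaks lay at most 92 bp from that of the BMAL1 partner. The partners ranked from 63 to 665 in the BMAL1 list, with scores from 33.5 to 74.

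Whether CLOCK occupied BMAL1 sites was asked by overlap. Of 269 CLOCK peaks, 140 overlapped a BMAL1 peak (52.0%, exact 95% interval 45.9 to 58.1%). Random placement gave a mean of 1.00 overlapping peaks (SD 1.01) and at most 7 in 10000 placements. The one-sided permutation p was 0.0001, the smallest these placements can give. Placements were spread evenly between the outermost peaks and did not follow where peaks of any factor tend to lie. The test thus shows more overlap than even placement gives, not what brought the peaks together. Seen from the other list, 140 of 9584 BMAL1 peaks were shared (1.46%, exact 95% interval 1.23 to 1.72%), and 9444 BMAL1 and 129 CLOCK peaks were not. With the higher-scoring part of each list, 4792 BMAL1 and 135 CLOCK peaks, 57 CLOCK peaks were shared (42.2%). Of all 269 CLOCK peaks, 72 (26.8%) overlapped a BMAL1 peak scoring 18 or more. Against only the 269 highest-scoring BMAL1 peaks, 16 (5.95%) did. The last 2 limits were chosen after the data were seen, and shorter lists must give fewer shared peaks. Random placement gave fewer as well, with means of 0.265 for the higher-scoring parts, 0.328 for scores of 18 or more and 0.0316 for the 269 highest.

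Shared peaks were closely aligned. The median distance between their midpoints was 50.5 bp, with quartiles of 12 and 122.5 bp and a greatest distance of 463 bp. The overlap rule and the peak widths limit this distance, so its greatest value is no finding. In 98 of the 140 pairs the midpoints lay within 100 bp, and in 80 the whole BMAL1 peak fell inside the CLOCK peak. Random placement gave a mean of 0.218 peaks with midpoints within 100 bp, and of 1.00 overlapping peaks. CLOCK peaks without overlap lay at a median of 59984 bp from the nearest BMAL1 midpoint. Of these 129, 7 lay within 1000 bp and 103 were more than 10000 bp away. No random value was computed for these distances, so they do not show that the peaks were unusually remote. Allowing a gap of up to 1000 bp raised the shared count from 140 to 149, and the random mean from 1.00 to 3.08. The strongest CLOCK peaks without overlap, chosen after their values were seen, were chr5:175874850-175875382 with a score of 74 and chr19:56165827-56166359 with 71.5. Their nearest BMAL1 midpoints were 18539 and 23657 bp away.

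**Figure D2:**
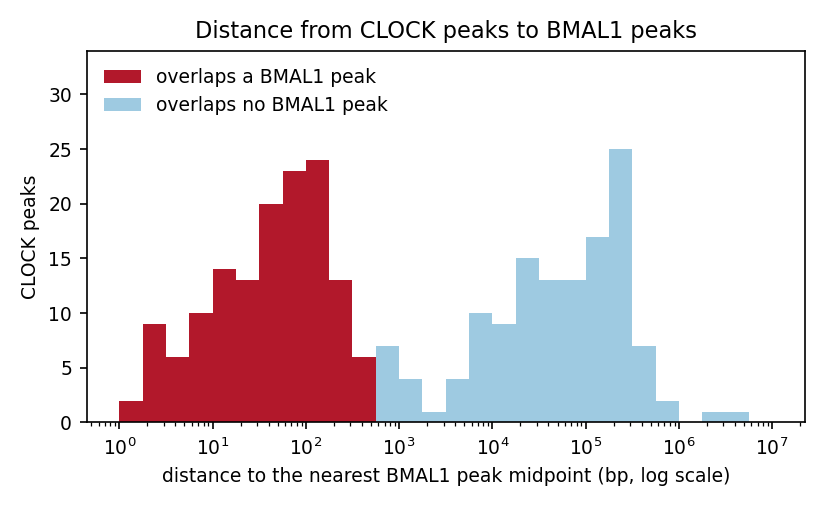
Number of CLOCK peaks (vertical axis) by distance from the midpoint to the nearest BMAL1 midpoint (horizontal axis, bp, log scale), coloured by overlap with a BMAL1 peak, with distances under 1 bp drawn at 1 bp. The 140 overlapping peaks lie within 463 bp, and 103 of the 129 others lie beyond 10000 bp.

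The shared regions with the best worst rank over both lists came from several chromosomes. Ranks were not scaled to list length, so the rank in the far longer BMAL1 list mostly set this order. The first was chr8:6149333-6149636, the bases common to a CLOCK peak scoring 67.5 and a BMAL1 peak scoring 126.5. On chromosome 1, chr1:229203907-229204303 had CLOCK and BMAL1 scores of 116 and 74, and chr1:228743605-228744001 had 42.5 and 69. The region chr4:2414678-2415074 had scores of 124.5 and 72 in the same order, and chr7:151620254-151620650 had 58.5 and 63.5. CLOCK scored 126.5 and BMAL1 58 at chr16:33889197-33889593, and 111.5 and 58 at chrX:153523642-153524014. At chr22:18688025-18688421 the scores were 169 and 57, and at chr10:88731028-88731424 they were 99.5 and 56.5. The last, chr19:823647-824043, had a CLOCK score of 22, below the CLOCK median of 24, and a BMAL1 score of 62.5.

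The authors' deposited table of common regions listed 140 regions, and all 140 equalled the bases shared by the CLOCK and BMAL1 peaks named in it. In the authors' deposited table the score was that of the CLOCK peak in 140 of 140 regions. Region widths in the authors' deposited table, again with both end positions counted, ran from 2 to 397 bp, with a median of 397 bp.

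BMAL1 peaks shared with CLOCK had higher scores than BMAL1 peaks in general. Their median score was 18, against 14.5 for the 9444 others. That median exceeded every one of 10000 random BMAL1 lists of 140 peaks, of which the highest had a median of 17.5. By score, 2.76% of the highest-scoring 20% of BMAL1 peaks were shared (exact 95% interval 2.08 to 3.60%), against 0.887% of the lowest 20% (0.518 to 1.42%). Of the 20 highest-scoring BMAL1 peaks 1 was shared, of the 50 highest also 1 (2%, exact 95% interval 0.0506 to 10.6%), and of the 100 highest 7 (7%, 2.86 to 13.9%). For CLOCK, the median score was 25.5 in shared and 22.5 in other peaks, at percentile 92.5 of random CLOCK lists, which is within their central 95% range of 23 to 25.75. In the highest-scoring 20% of CLOCK peaks 37 of 54 were shared (68.5%, exact 95% interval 54.4 to 80.5%), and in the lowest 20% 24 of 53 (45.3%, 31.6 to 59.6%).

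**Figure D3:**
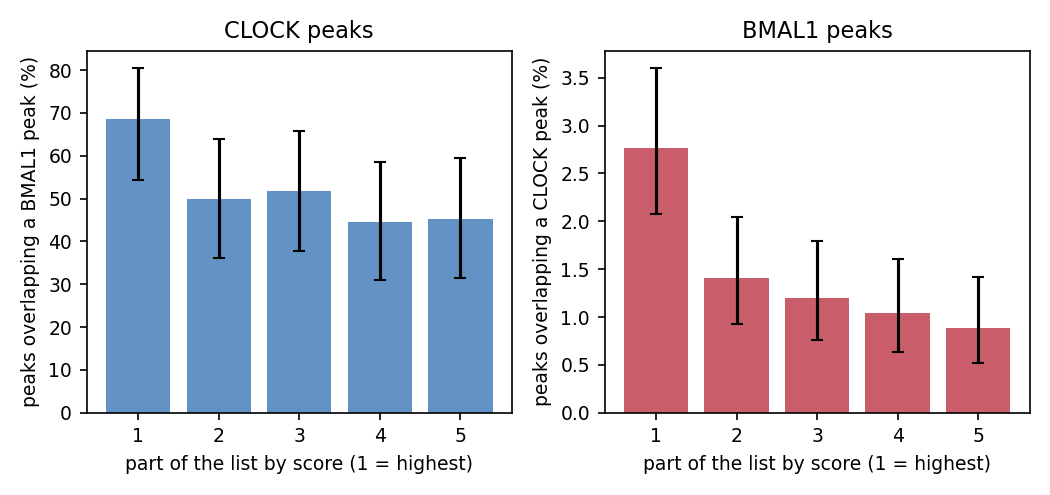
Percent of peaks that overlap a peak of the other factor (vertical axes, on different scales) in 5 equal parts of the CLOCK list (left) and the BMAL1 list (right) ordered by score, with 1 the highest. Bars are shares and error bars exact 95% binomial intervals, from 68.5% in the highest CLOCK part and 2.76% in the highest BMAL1 part.

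Across the 140 shared peaks, CLOCK and BMAL1 scores were positively correlated, with Pearson r = 0.51 (permutation p = 1e-05, the smallest the resampling can give) and Spearman rho = 0.27 (permutation p = 0.00118). Without the 2 peaks farthest from the median BMAL1 score, r was 0.56 and rho 0.28. This check left out no peak for its CLOCK score. The 10 highest-scoring CLOCK peaks had partners scoring 33.5 to 74, against a median of 18 for shared BMAL1 peaks. Pearson's r may rest in part on these few peaks, and it was not computed without them. These correlations run across peaks, which are not independent replicates.

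Peaks were spread over the chromosomes unevenly. Chromosome 1 held 1187 BMAL1 peaks (12.4%) and chromosome 19 held 28 CLOCK peaks (10.4%), the largest number of each list. Per Mb between the outermost peaks, chromosome 19 was densest for both factors, with 7.38 BMAL1 and 0.476 CLOCK peaks. Chromosome X had 0.819 BMAL1 peaks per Mb, the lowest of chromosomes 1 to 22 and X. On chromosome 6 only 2 of 18 CLOCK peaks were shared, while on chromosome 19 16 of 28 were.

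**Figure D4:**
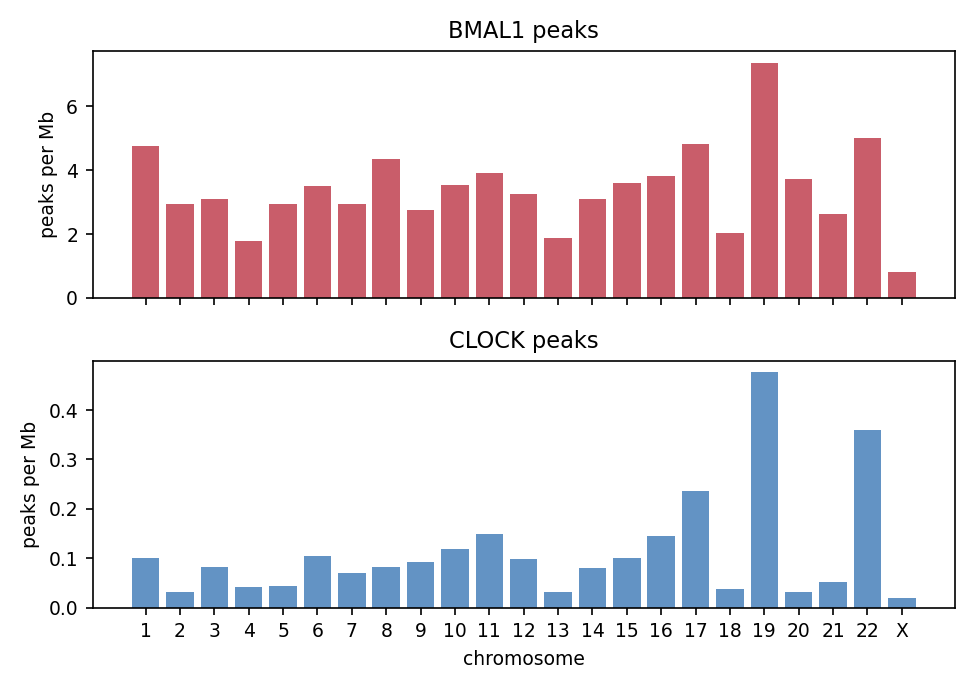
Peaks per Mb (vertical axes, on different scales) of BMAL1 (top) and CLOCK (bottom) on chromosomes 1 to 22 and X, over the span between the outermost peaks of either list. Chromosome 19 stands highest in both, at 7.38 BMAL1 and 0.476 CLOCK peaks per Mb.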

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

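The peak numbers in the lists were examined only after the other results were seen. Within each chromosome the number rose as the score fell, with 0 exceptions among 9560 neighbouring BMAL1 pairs and 0 among 245 CLOCK pairs, so gaps in the numbering mark ranks absent from the lists. On chromosome 1, 1831 CLOCK numbers and 1623 BMAL1 numbers were absent, a signal in a column that no test above uses. The next highest were 416 CLOCK numbers on chromosome 6 and 344 BMAL1 numbers on chromosome 8. Absent ranks included high ones: on chromosome 1, 334 CLOCK numbers were absent between a peak scoring 116 and the next, scoring 48. The percent of absent numbers per chromosome was correlated between the factors, with Pearson r = 0.57 (permutation p = 0.00194) and Spearman rho = 0.78 (permutation p = 2e-05) over 24 chromosomes. Without the 2 chromosomes farthest from the median BMAL1 percent, 1 and Y, r was 0.69 and rho 0.71. The CLOCK percent depends on the highest listed number, which rests on few peaks on some chromosomes, such as 1 on Y and 2 each on 20 and 21. The positions and the reason for the absence of these ranks were not examined, and no explanation was tested.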

How the results depend on the processing

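The limits on BMAL1 peaks alone and the removal of chromosome 1, chromosome 6, chromosome 1 from 40 to 44 Mb or peaks beside BMAL1-free stretches were chosen after the data were seen. Of 28 alternatives to 8 results, 23 left the result on the same side of its test or within its limit and 5 moved a count by more than 1.5 times. Some of the 23 could hardly change a result, such as leaving out chromosome Y, or a coverage rule for deposited regions that equal the shared bases. The tally is therefore no measure of robustness. Keeping the higher-scoring part of each list left 4792 BMAL1 and 135 CLOCK peaks, by construction, and 57 shared peaks. With BMAL1 peaks scoring 18 or more, a limit borrowed from the CLOCK list although no shared scale is stated, 72 CLOCK peaks were shared, and with as many top BMAL1 peaks as CLOCK peaks 16 were, as shorter lists must give fewer. In all 12 alternatives of the overlap the permutation p was 0.0001, the smallest possible. Random placements gave at most 11 peaks under any of them, so this p does not separate the settings. Other overlap rules gave 98 to 149 shared peaks. Spearman's rho over shared peaks ranged from 0.24 to 0.28 over its alternatives.

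No paired analysis was possible because the NOMO-1 libraries that share replicate numbers have no peak list used here. Tests of promoters, E-box sequences and gene lists, and their alternative settings, were not run. The depth of the libraries is unknown, so the absence of a site from a list does not show that it was unbound.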

Other observations

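All tests in this part were chosen after the results were seen, except the random shift of CLOCK peaks. On chromosome 6, 9 CLOCK peaks lay between 26027292 and 27841696, with scores from 18.5 to 37, and 0 overlapped a BMAL1 peak (exact 95% upper limit 33.6%), against 53.8% of the 260 CLOCK peaks elsewhere. The nearest BMAL1 midpoints were 142770 to 466337 bp away. From 26 to 28 Mb only 4 BMAL1 peaks were listed, and 339 of 934 BMAL1 peak numbers of chromosome 6 were absent at unknown positions. BMAL1 peaks at these sites thus cannot be excluded. The upper limit also treats these neighbouring peaks as independent. No other chromosome had more than 5 CLOCK peaks in 2 Mb. With a limit of 30000 bp between neighbours, 3 pairs of shared CLOCK peaks were found. They lay at chr11:45868573-45869105 and chr11:45881133-45881665, with midpoints 12560 bp apart, at chr17:38255307-38255839 and chr17:38264281-38264813, 8974 bp apart, and at chr19:796816-797348 and chr19:823592-824124, 26776 bp apart.

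BMAL1 scores along chromosome 1 from 40 to 44 Mb, a region chosen because they were high, included 14 of the 20 highest, with quartiles of 38.75 and 133. The upper quartile of the other chromosome 1 peaks was 23. The highest median of 20 listed peaks in a row was 129 here and 31 elsewhere. Among listed peaks, high scores were thus not confined to a few. Raised scores continued past its edge to a BMAL1 peak scoring 49 that is shared with the CLOCK peak chr1:44300188-44300720, scoring 40. More copies of the region in this cell line may raise all scores there, but the 0 CLOCK peaks inside the chosen edges, or 1 with this neighbour, are too few to decide it. On chromosome 1, 98.7% of the CLOCK and 57.8% of the BMAL1 peak numbers were absent at unknown positions, so strong sites among ordinary ones that were not listed stay open too. The input library was not analysed here, and no biological explanation was tested.

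For the overlap of 140 CLOCK peaks with BMAL1 peaks, random shifts of 10000 to 100000 bp left a mean of 2.04 and at most 9. This argues against the density of BMAL1 peaks over such distances as its source. Clustering within 10000 bp cannot be seen by these shifts. If peaks merely clustered over 1000 to 10000 bp, more CLOCK peaks would lie near a BMAL1 peak than overlap it. Yet 140 overlapped, while 26 of the 129 others lay within 10000 bp of a BMAL1 midpoint, 7 of them within 1000 bp. Merging BMAL1 peaks within 1000 bp left 9461 of 9584, so few lay that close together. These values argue against clustering over 1000 to 10000 bp as the source. Closer clustering stays open. Regions beside long peak-free stretches, which may recur in many libraries, were examined only at the longest BMAL1-free stretch of each chromosome. More than 2 Mb from it, 131 of 251 CLOCK peaks were shared (52.2%, exact 95% interval 45.8 to 58.5%). Within 2 Mb, 9 of 18 were shared. As only 18 CLOCK peaks lay this near, the share elsewhere could not have been low and tests little. That only 9 shared peaks lay near shows no more than that regions beside the longest stretches are not the whole source. Other peak-free stretches were not examined and stay open. Other regions that are enriched with any antibody stay open too, as the IgG and input libraries were not analysed here. Joint binding of the heterodimer stays open and was not tested.

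BMAL1 peaks shared with CLOCK came from every score range. From the highest-scoring 20% of the BMAL1 list to the lowest, 53, 27, 23, 20 and 17 peaks were shared.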
